A study of Homo sapiens with 3 samples.

How the data were processed

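Exon inclusion was compared in BJ fibroblasts, an established line of human foreskin fibroblasts, 8 days after induction of the reprogramming factors OCT4, SOX2, KLF4 and MYC (OSKM). Per the labels, 1 sample received a non-targeting siRNA, 1 received SMAD3 siRNA and 1 received SFRS11 siRNA. SMAD3 is a transcription factor that transmits TGF-beta signals, and SFRS11 (current symbol SRSF11) is a splicing factor with an arginine and serine rich domain. Each group thus had 1 library. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, purified on a column, selected for mRNA and made into TruSeq libraries.

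The submitters' processing notes name the genome build hg19, the aligner STAR and the quality tool FastQC, without versions. The program that called and tested the splicing events is not given in the sources used here. The authors deposited 2 tables of exon-skipping events, which compare the libraries coded RS2 and RS3 each with 1 other library, called the comparator library here. Each row is 1 skipped exon with its gene, its coordinates and, per the file headers, a p-value, an FDR and a difference in inclusion level. Inclusion level is the share of a gene's transcripts over that region that keep the exon, so the deposited difference runs from -1 to 1.

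No label or header ties RS2, RS3 or the comparator library to a siRNA. The codes are therefore kept throughout, and no statement is made about which table belongs to which knockdown or whether the comparator is the non-targeting library. The 4 columns of inclusion level per library, 2 in each table, entered no result for the same reason. They were looked at once, outside the scripts, to settle the sign: the deposited difference was taken as the level listed first minus the level listed second, with the second from the library both tables share. No table of results here holds that look. A positive difference is therefore read as higher inclusion than in the comparator library.

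An event was called when the authors' deposited FDR was under 0.05 and the absolute difference was at least 0.1. The deposited p-values and FDR compare 2 libraries and not 2 conditions, because no group has a replicate. A Benjamini-Hochberg adjustment of the deposited p-values moved 0 events across the FDR threshold in either table. Read counts were not used here, so the depth behind each value is unknown and no interval is given for single differences.

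The tables list the skipped exon without its flanking exons, and 5354 exons of the RS2 table and 5724 of the RS3 table appear in more than 1 row. The design had planned to match events between tables on the skipped exon and its flanks. Exons were matched instead on gene, strand, start and end, and an exon counted as called if any of its rows was. Where a value of the same exon in the other table is given for an exon with several rows there, it is that of the row with the smallest p-value. Coordinates are those of the deposited tables in hg19, counted from 1. The annotation at hand was GENCODE release 29 on GRCh38, with which 274 of 39321 exons (0.697%) coincided by position, so it was used for no coordinate.

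Gene symbols were taken from the tables. In both tables, symbols of 17 gene identifiers (16 distinct symbols) had been turned into dates, and these were restored through the Ensembl identifier. Of the gene identifiers, 10373 of 10526 in the RS2 table and 10575 of 10723 in the RS3 table were in the name table.

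The tests, the 14 gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The named events were, per table, the 10 called events with the largest difference in each direction with at most 1 per gene, up to 3 called genes of each list, and every event of SMAD3 and SRSF11. The 5 exons called in both tables with the largest smaller difference were also named. Some genes that meet this rule are not reported here, though they are part of the counts. The lists covered SR proteins and related factors, hnRNPs and tissue-specific splicing regulators, the spliceosome core, TGF-beta and BMP signalling, genes with splicing changes in epithelial-mesenchymal transition (EMT), pluripotency factors, and chromatin regulators. They also covered fibroblast extracellular matrix and adhesion, the actin cytoskeleton, apoptosis and the p53 pathway, cell cycle, DNA repair, epithelial markers and neural markers.

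For each list, the number of genes with a called event was set beside 10000 random lists of the same size, matched on the number of tested events per gene. Exon length was compared with 10000 random draws of as many tested events. These percentiles describe these libraries and are not tests of the conditions. The overlap of calls was set beside the product of both counts over the exons listed in both tables. It was also set beside 1000 simulations of unchanged libraries that share a comparator, with an assumed correlation of 0.5 between the differences, called either at the largest p-value among the observed calls or with as many calls as observed. Ratios of differences have 95% bootstrap intervals from 10000 resamples of exons, which are not independent replicates.

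The counting steps were tested on simulated data with 200 changed events per table and assumed errors of 0.05 or 0.12. Of events changed by 0.2, 25.0% were recovered in a simulation of the RS2 table (40702 events) and 27.5% in a simulation of the RS3 table (42518 events). Of events changed by 0.4, 70.0% and 67.0% were recovered. At most 5.4% of the simulated calls were false. The simulations took only the number of events from each table, so they do not measure how sensitive either real table is. Alternatives covered the FDR, the minimum difference, the adjustment, the counting of repeated exons and the matching of exons. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.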

Results

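The data were 2 deposited tables of exon-skipping events, which compared 3 libraries of BJ fibroblasts on day 8 of OSKM reprogramming. The cells had received non-targeting, SMAD3 or SFRS11 siRNA, with 1 library per group and no replicates. The RS2 table listed 40702 events in 33745 exons of 10486 genes. The RS3 table listed 42518 events in 34977 exons of 10684 genes. Every difference below is from the authors' deposited table and means inclusion in RS2 or RS3 minus inclusion in the comparator library that both tables share. RS2, RS3 and the comparator are not tied to the siRNAs by any label, and read depth is unknown.

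The targeted genes had no called event in either table. SMAD3 (ENSG00000166949) had 3 tested exons on chromosome 15, and the differences in the authors' deposited table lay between -0.001 and 0.013 in RS2 and between -0.009 and 0.008 in RS3. For SRSF11 (ENSG00000116754, chromosome 1) the largest RS2 difference in the authors' deposited table was -0.281, with an FDR of 1. Its largest RS3 difference in the authors' deposited table was -0.143, at the exon from 70697542 to 70697658, with an FDR of 0.115. Inclusion levels do not measure the amount of a gene's RNA, so these values do not check the knockdowns.

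The RS2 comparison asked which exons were included differently in RS2 than in the comparator. Few exons were called: 29 events in 25 genes, 11 with higher and 18 with lower inclusion. Exons of matrix and cytoskeletal genes were among them. Inclusion fell by 0.201 in the authors' deposited table for a 273-base exon of FN1, fibronectin (chromosome 2, 216257654 to 216257926), with a listed FDR of 0.

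The largest RS2 gains in the authors' deposited table were in KIAA1841 (0.351, FDR 0.00613) and HDAC10, a polyamine deacetylase (0.347, FDR 0.00522). GMIP followed at 0.233 and MICAL3 at 0.209 in the authors' deposited table. Smaller gains in the authors' deposited table were those of PLD3 (0.157), the matrix glycoprotein tenascin-C gene TNC (0.136), HP1BP3 (0.131), the histone chaperone gene NAP1L4 (0.122) and the formin gene INF2 (0.103). The largest losses in the authors' deposited table were in SUOX, sulfite oxidase (-0.350, FDR 0.00613), DCTD, deoxycytidylate deaminase (-0.347, FDR 0.0176), and RAB11FIP3, a Rab11 effector of endosome recycling (-0.286, FDR 0.0270). Losses in the authors' deposited table were also called in ECHDC2 (-0.203), SSBP3 (-0.192), C1orf52 (-0.190), BIN1, which shapes membranes (-0.183), and the pyruvate dehydrogenase phosphatase PDP1 (-0.161).

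Of the gene lists in RS2, the EMT-associated list had 3 of 50 tested genes with a called event, against 0.238% of all genes. INF2 rose, and the growth factor receptor gene FGFR1 fell by 0.128 in the authors' deposited table. Of 10000 matched random lists, 52 reached that count. The actin list had 3 of 65 genes, among them INF2 with higher inclusion and ACTN1, alpha-actinin, with lower inclusion (-0.128 in the authors' deposited table), and 50 random lists reached it. The matrix and adhesion list had FN1 and TNC among 57 tested genes, a count that 558 random lists reached. The remaining 11 lists, which include the splicing factor and TGF-beta lists, had 0 called genes in RS2. With an FDR under 0.01 and a difference of at least 0.2, the EMT, actin and matrix lists each had 1 called gene in RS2.

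With a minimum difference of 0.2, 11 RS2 events were left and the share with lower inclusion went from 62.1% to 45.5%. Of the 22 named RS2 exons, 12 were listed in several rows and 4 of these (PLD3, HP1BP3, INF2 and FGFR1) had rows of both signs. The RS2 value printed for such exons is that of a called row. In the authors' deposited table other rows were near 0 for DCTD (-0.014 and -0.046), PDP1 (-0.007) and TNC (0.005 and 0.025). The rows of the KIAA1841 exon ranged from 0.048 to 0.429.

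The RS3 comparison asked the same of RS3 and the comparator. Many more exons were called than in RS2: 411 events in 327 genes. Inclusion was lower in 313 of these events (76.2%) and higher in 98. Some switches were large. In the authors' deposited table, inclusion fell by 0.781 for a 50-base exon of MTO1, a mitochondrial tRNA-modifying enzyme (chromosome 6, 74190041 to 74190090, FDR 6.1e-05). The MTO1 exon differed by 0.043 in RS2 in the authors' deposited table, with an FDR of 1. A 60-base exon of MFF, which recruits the fission machinery to mitochondria (chromosome 2, 228217230 to 228217289), had 3 rows in RS3 in the authors' deposited table. They were -0.706 (FDR 5.65e-07), -0.308 (FDR 0.32) and -0.052 (FDR 1), of which only the first was called. Its single RS2 row in the authors' deposited table was -0.017 (FDR 1), and which RS3 row this matches is unknown.

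**Figure D1:**
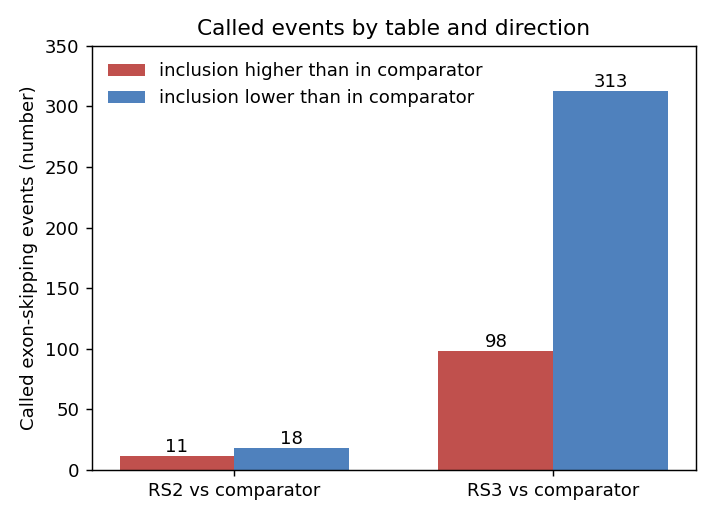
Number of called exon-skipping events (vertical axis) in the RS2 and RS3 tables, with separate bars for inclusion higher and lower than in the comparator library. RS2 had 11 higher and 18 lower events, and RS3 had 98 higher and 313 lower.

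Other exons with lower inclusion in RS3 in the authors' deposited table belonged to the zinc-finger genes ZNF133 (-0.657), ZNF684 (-0.623) and ZNF138 (-0.622). The authors' deposited table also listed losses in AC069513.3 (-0.766), DPCD (-0.594), the adipogenic nuclear receptor PPARG (-0.567), the heparan sulfate endosulfatase SULF1 (-0.515, FDR listed as 0) and ANKDD1A (-0.507). The largest gain in the authors' deposited table was that of a 42-base exon of the scaffold gene MAGI2 (0.698, FDR 0.0215). It was followed in the authors' deposited table by WASF1, a component of the WAVE actin-regulating complex (0.552), CANT1 (0.451), XRRA1 (0.398) and the kinase gene AKT1 (0.386). Gains in the authors' deposited table were further called in BTN3A2 (0.353), KANK2 (0.320), HERC2P9 (0.313) and the ribonuclease inhibitor RNH1 (0.309). IFI27L1 had 4 called events in the authors' deposited table, 1 gain (0.355, FDR 0.0227) and 3 losses (-0.448 with an FDR of 0.00848, -0.431 with an FDR of 2.73e-08 and -0.390 with an FDR of 0.0225).

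**Figure D2:**
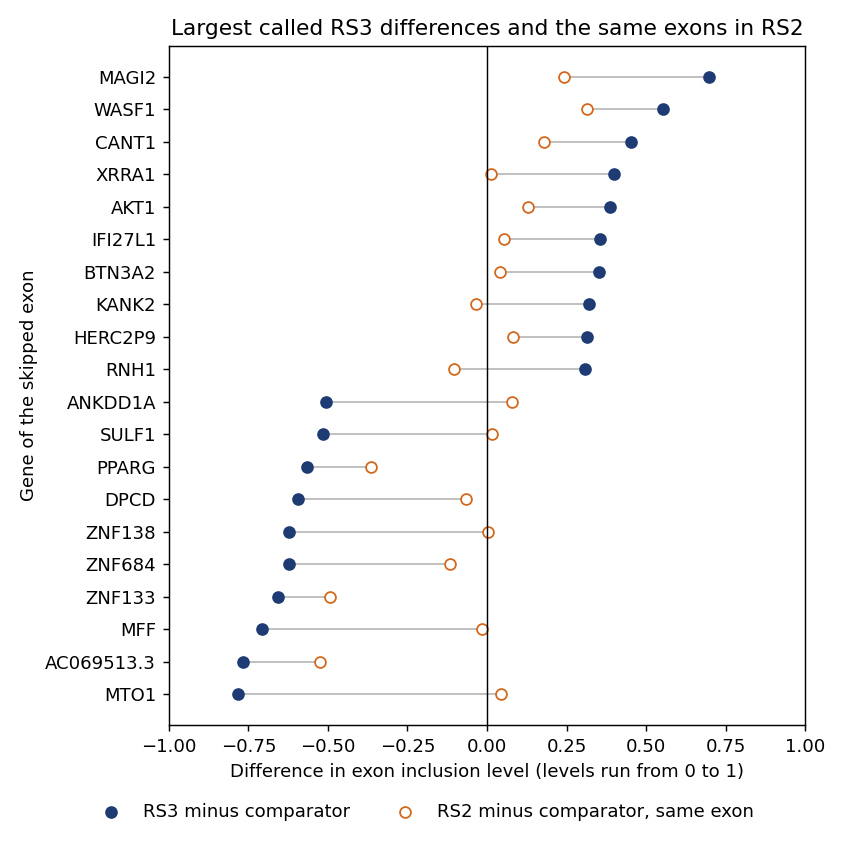
Difference in inclusion level (horizontal axis, on a scale where levels run from 0 to 1) for the 10 largest called gains and 10 largest called losses of RS3. Filled points are RS3 minus the comparator and open points are RS2 minus the comparator for the same exon, by its row of smallest p-value where there are several; MTO1 lies at -0.781 in RS3 and 0.043 in RS2, whereas ZNF133 lies at -0.657 and -0.493.

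Of the 47 named RS3 exons, 20 were listed in several rows and 7 (WASF1, IFI27L1, AC069513.3, ZNF133, ANKDD1A, KDM1A and POLL) had rows of both signs. For exons in several rows the value printed is that of a called row. Other rows were near 0 for some, such as COL6A3 (-0.008), BIRC5 (-0.009), NUMB (-0.002) and CANT1 (0.012) in the authors' deposited table. WASF1 ranged from -0.364 to 0.552 and ZNF133 from -0.657 to 0.292 over the rows of 1 exon in the authors' deposited table, and the IFI27L1 rows of -0.390 and 0.355 are of the same exon.

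Genes with known splicing changes in EMT stood out among the lists in RS3. Of 50 tested genes, 14 (28.0%) had a called event, 12 with lower and 2 with higher inclusion, against 3.06% of all genes. Examples in the authors' deposited table are a 12-base exon of the endocytic GTPase gene DNM2 (-0.341), OSBPL3 (-0.339) and the tumor suppressor gene NF2 (-0.266). The random lists had a median of 3 such genes and 0 of 10000 reached 14; adjusted over the list alone, 15 genes had a called event.

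The actin cytoskeleton list also had more called genes than most random lists. Events were called in 10 of 66 genes, 7 with lower and 4 with higher inclusion, as WASF1 had both. Inclusion was lower for ACTN1 (-0.363) and for MYO5A, a myosin motor (-0.306), in the authors' deposited table. The ACTN1 exon had another row at -0.043 in the authors' deposited table. Of 10000 random lists, 21 reached this count, and 11 genes had a called event adjusted over the list alone. The EMT and actin lists share 7 genes.

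**Figure D3:**
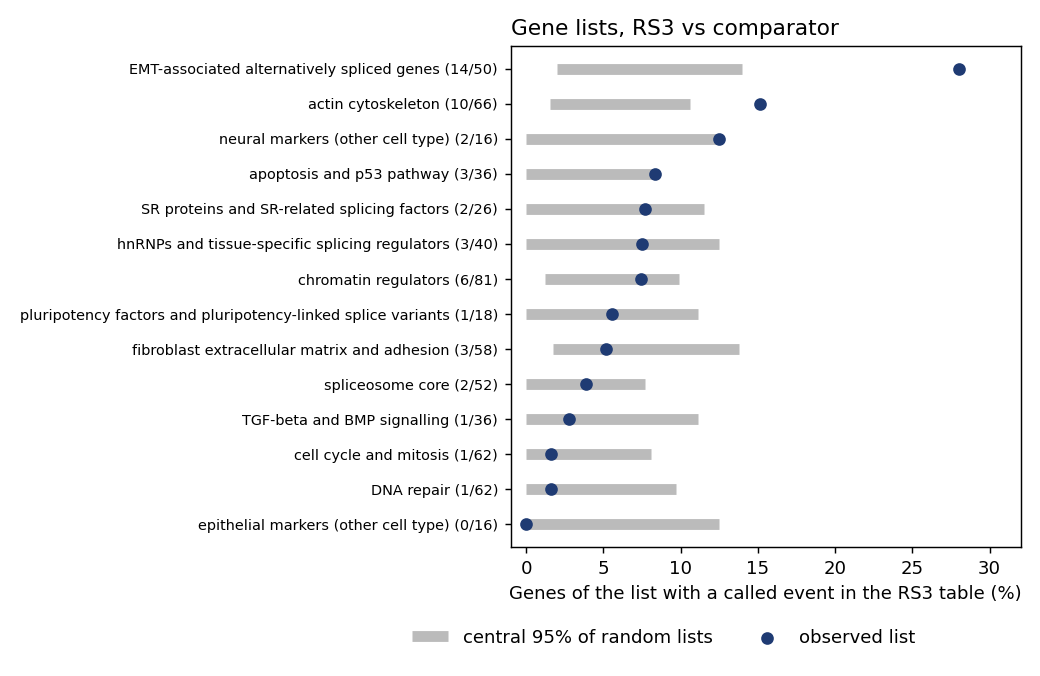
Percentage of tested genes with a called RS3 event in each list (horizontal axis), with called and tested genes in brackets. Points are the lists and grey bars the central 95% of 10000 random lists matched on tested events per gene; the EMT-associated list (28.0%) and the actin list (15.2%) lie beyond their bars.

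Splicing regulators had single called exons in RS3. Among hnRNPs and tissue-specific regulators, 3 of 40 genes had lower inclusion, namely HNRNPA2B1 (-0.407), MBNL2 (-0.200) and MBNL1 (-0.199) in the authors' deposited table. The spliceosome core list had PUF60 (-0.262) and the U1 component SNRPC (-0.199) in the authors' deposited table, out of 52 genes. Of 26 SR proteins and related factors, SRRM1 rose by 0.150 and ACIN1 fell by 0.149 in the authors' deposited table. Random lists reached these counts 4088, 4519 and 1701 times of 10000.

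Chromatin regulators had 6 of 81 genes called in RS3, 4 lower and 2 higher. Inclusion was lower for the acetyltransferase gene CREBBP (-0.399) and the demethylase gene KDM1A (-0.171), and higher for the DNA methyltransferase gene DNMT1 (0.145), in the authors' deposited table. The KDM1A exon had another row at 0.001 (FDR 1) in the authors' deposited table. The matrix and adhesion list had 3 of 58 genes, all lower: the integrin gene ITGB5 (-0.270), FN1 (-0.194) and the collagen gene COL6A3 (-0.102) in the authors' deposited table. In the apoptosis list, BIRC5 (-0.142), NUMB (-0.110) and BCL2L12 (0.114) were called among 36 genes in the authors' deposited table. Of 10000 random lists, 1701, 7799 and 742 reached these counts.

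The remaining lists had few called genes in RS3. In the authors' deposited table the TGF-beta list had only TGFB2 (0.172) among 36 genes, the pluripotency list ZNF207 (0.197) among 18, the cell cycle list AURKB (-0.153) among 62 and the DNA repair list POLL (-0.147) among 62. Random lists reached a count of 1 in 7797, 3454, 9154 and 9365 of 10000 draws. Of the markers of other cell types, 0 of 16 epithelial genes were called, and of 16 neural genes MAP2 (-0.239) and APP (-0.138) were called in the authors' deposited table, a count that 993 random lists reached. These tables measure splicing, so they do not show whether marker genes were expressed more or less. With an FDR under 0.01 and a difference of at least 0.2, 5 genes of the EMT list and 4 of the actin list were left, and 8 of the other lists with calls fell to 0.

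Called exons were then compared between the tables. Of 29288 exons listed in both, 27 were called in RS2, 392 in RS3 and 11 in both, all 11 in the same direction (4 higher and 7 lower). In the authors' deposited table, HDAC10 was higher by 0.347 in RS2 and 0.309 in RS3, and GMIP by 0.233 and 0.244. Inclusion was lower in both for RAB11FIP3 (-0.286 and -0.304), ECHDC2 (-0.203 and -0.266) and FN1 (-0.201 and -0.194) in the authors' deposited table. Exons of ACTN1 and FGFR1 and another exon form of ECHDC2 were also called in both.

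Independent lists of these sizes would share 0.361 exons, of which 0.0353 higher and 0.163 lower. Simulated unchanged libraries with a shared comparator, called at the p-values of the observed calls, had 1.56 and 23.3 calls on average and shared 0.123 exons, at most 3. With as many calls as observed, such libraries shared 5.81 exons on average and at most 13, and 19 of 1000 simulations reached 11. Both tables use the same comparator library, which cannot be split, so part of the excess may come from that library itself. With an FDR under 0.01 and a difference of at least 0.2, 2 exons were called in both.

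Most exons called in RS3 were not alike in RS2. Of the 392, 231 (58.9%) had a difference of opposite sign or under 0.05 in size in RS2, and 109 had the opposite sign. Over the 218 RS3-called exons in a single row of each table, 76.6% had the same sign in RS2. SULF1 (0.015), CREBBP (0.005) and XRRA1 (0.011) were near 0 in RS2 in the authors' deposited table. Other exons with large RS3 differences went the same way in RS2 without being called there. Examples in the authors' deposited table are PPARG (-0.364), MAGI2 (0.242) and AKT1 (0.128) in RS2. Of the 27 exons called in RS2, 6 were not alike in RS3, among them KIAA1841 with -0.016 in the authors' deposited table. A direct test of RS3 against RS2 was not made, since read counts were not used. With a limit of 0.1 in place of 0.05, 12 of the 27 and 305 of the 392 exons were not alike. The counts of 27 and 392 include exons in several rows, for which the rows set beside each other may not match.

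Exon lengths of called events were set beside those of all tested events. In RS3, 51.6% of called events had an exon length that is a multiple of 3, against 41.2% of all events, and 0 of 10000 random draws were higher. The share was 54.0% for the 313 events with lower inclusion (0 draws higher) and 43.9% for the 98 with higher inclusion (2597 draws higher); the directions were not tested against each other. The median length in RS3 was 109 bases against 120, and 2 draws were lower; it was 105 for lower and 112 for higher events, for which 2 and 1207 draws were lower. Exons of at most 51 bases made up 11.7% of called events against 6.29%, and 0 draws were higher. In RS2, 69.0% of the called lengths were multiples of 3 against 41.1%, and 6 draws were higher; the share was 77.8% for the 18 lower events (2 draws higher) and 54.5% for the 11 higher events (1112 draws higher). The median length was 121 bases against 119, with 5401 draws lower and 4347 higher, but this joins 126.5 for the lower events (6853 draws lower) and 72 for the higher events (42 draws lower). Exons of at most 51 bases made up 17.2% of the called RS2 events against 6.37%, and 95 draws were higher. This share was 5.56% for the lower events (3127 draws higher) and 36.4% for the higher events (4 draws higher).

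Over all events the median difference was near 0 in both tables. The mean was 0.00118 in RS2 and -0.0112 in RS3, which thus leaned towards lower inclusion. The median difference in the authors' deposited table was 0 in RS2 (quartiles -0.016 and 0.019) and -0.001 in RS3 (quartiles -0.027 and 0.014). Differences of at least 0.1 were listed for 19.2% of RS2 events and 21.2% of RS3 events, called ones included, and 7805 and 8585 events of that size were not called.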

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

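The counts of lower events with 1 event per gene and among uncalled events, the ratio over the most firmly called exons, and the comparison of opposite values below were chosen after the results were seen. The last took named exons called in 1 table with a difference of at least 0.1 the other way in the other table, after a search for exons called in opposite directions in both tables had found none.

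Inclusion of the C1orf52 exon at 85724618 to 85724744 on chromosome 1 stood out because RS2 and RS3 lay on opposite sides of the comparator, with -0.190 (FDR 0.000441) in RS2 and 0.128 (FDR 0.12) in RS3 in the authors' deposited table. The RNH1 exon at 504824 to 504996 on chromosome 11 stood out in the same way, with 0.309 (FDR 4.34e-05) in RS3 and -0.103 (FDR 0.844) in RS2 in the authors' deposited table, where it has 4 rows in each. The opposite sign rests on 1 of the 4 RS2 rows: the others in the authors' deposited table are 0.006, 0.021 and -0.001 in RS2, and 0.078, 0.04 and 0.108 in RS3. Without flanking exons the rows cannot be paired between the tables. The difference between RS2 and RS3 was not tested for either exon.

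RS3 had 411 called events and RS2 had 29. If both libraries differed from the comparator alike and only RS3 had the depth to show it, the same exons would differ about equally in RS2, but the median ratio of the RS2 to the RS3 difference was 0.172 (95% bootstrap interval 0.12 to 0.228, 218 exons in a single row of each table). Choosing exons by their RS3 call enlarges RS3 differences and so lowers this ratio. Over the 76 of these exons that pass a Bonferroni adjustment the ratio was 0.107 (0.0619 to 0.184). Those 76 were also chosen by their RS3 p-value, so the enlargement is not removed. Of the 27 exons called in RS2, 6 were not alike in RS3. For exons chosen in RS3 the ratios argue against depth as the whole cause, but how far the choice lowered them was not measured. A partial effect of depth stays open, and a different effect of the siRNAs was not tested, because the codes are tied to no siRNA and each group has 1 library.

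Called RS3 events were mostly lower in inclusion, 313 of 411. Repeated rows do not account for this, since 76.9% of calls were lower with 1 event per gene. As the whole cause, a comparator library that stands apart from both others is argued against by the exons called lower in RS3. Their RS2 differences were 0.172 of the RS3 ones at the median (95% bootstrap interval 0.117 to 0.263, 153 exons). Choosing these exons by their RS3 call lowers this ratio too, by an amount that was not measured. Of these exons, 77.1% had the same sign in RS2, so a partial role of the comparator stays open. A tilt of all events in the RS3 library cannot be told apart from a change in these exons: among 8585 uncalled events of at least 0.1, 57.3% were lower in RS3, between the share in the called events and an even split, against 49.4% of 7805 in RS2. A biological cause was not tested, for the reason given for the number of calls.

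The EMT-associated list had 14 of 50 genes called in RS3. That genes of the list are better measured than other genes is argued against by random lists matched on events per gene and on the gene's median absolute difference in RS2: 0 of 10000 reached 14, with a median of 4 and a maximum of 13. Read depth itself was not matched. The list was drawn up from genes known to be alternatively spliced, so its exons may move more readily in any comparison, which stays open. An effect of either siRNA on these exons is a hypothesis that these tables cannot test.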

How the results depend on the processing

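The overlap restricted to exons in a single row of each table, the share of lower events under each setting, the list draws matched on a second property and the simulation with as many calls as observed were added after the data were seen. The count of called events stayed within 1.5 times its value at an FDR of 0.1, with a minimum difference of 0.05, with each exon or gene counted once, with a recomputed Benjamini-Hochberg adjustment and without differences of exactly 1. It ranged from 24 to 42 in RS2 and from 308 to 565 in RS3 there. By construction, stricter or looser limits gave fewer or more calls: 19 in RS2 and 261 in RS3 at an FDR under 0.01, 11 and 189 with a difference of at least 0.2, 10 and 146 with Bonferroni, and 67 and 699 with no minimum difference. RS3 had more calls than RS2 under each of these settings. The share of lower events in RS2 reversed to 45.5% with a difference of at least 0.2, where 11 events are left, and the cause was not tested. It was 80.0% of 10 events with Bonferroni and between 58.3% and 64.9% under the other settings, so a direction in RS2 rests on few events. In RS3 it lay between 72.2% and 79.4%. The overlap was 2 exons at an FDR under 0.01 and a difference of at least 0.2 and 8 over exons in a single row. By gene it was 11, with 10 in the same direction. That count joins different exons of a gene, as BIN1 and MICAL3 were called at different exons in RS2 and RS3. The MICAL3 exons differed by 0.209 in RS2 and by -0.451 in RS3 in the authors' deposited table. At an FDR under 0.01 and a difference of at least 0.2, each RS2 list with calls (EMT, actin and matrix) fell to 1 gene. In RS3 the EMT list fell to 5, the actin list to 4, hnRNPs to 2, and the spliceosome and chromatin lists to 1. The SR, TGF-beta, pluripotency, matrix, apoptosis, cell cycle, DNA repair and neural lists had 0. With no minimum difference, the RS3 EMT and actin lists had 20 and 18 genes. Random lists were drawn at the reported setting only. With a limit of 0.1, 12 RS2 exons were not alike in RS3. Over events with a p-value under 1, the medians were 0.001 in RS2 and -0.006 in RS3. Of the 22 named RS2 events, 7 lost their call at an FDR under 0.01, 12 with a difference of at least 0.2 and 14 with Bonferroni; of the 47 in RS3, 16, 16 and 24 did.

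Fisher's exact test on junction reads and a minimum of junction reads were not run, since no read counts were used. Without replicates, leaving out a library was not possible. No paired analysis was possible because each group has 1 library. Depth is unknown, so it cannot be said which uncalled differences were too thinly covered to be called.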

Other observations

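The genes in the next paragraph and the zinc-finger test were chosen after the results were seen. No enrichment was tested for these genes, and they are given as values.

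Beyond MFF, its partner in mitochondrial division DNM1L had a called 78-base exon in RS3 in the authors' deposited table (-0.172, FDR 0.0236), and the same exon was at -0.063 in RS2. Exons of PDHA1, a pyruvate dehydrogenase subunit (-0.170), and SDHAF2, a succinate dehydrogenase assembly factor (-0.299), were also called lower in RS3 in the authors' deposited table. Next to PPARG, the nuclear receptor coactivator NCOA1 (-0.346) had lower inclusion in RS3, and the same exon was at -0.221 in RS2 in the authors' deposited table, where it was not called. Microexons of 12 bases were called lower in DNM2 (-0.341), the syntaxin gene STX16 (-0.291) and the retromer gene VPS29 (-0.197) in RS3 in the authors' deposited table. In innate immune signalling, the authors' deposited table listed called RS3 differences in IKBKB (-0.392), TIRAP (-0.331), TLR4 (-0.267) and IRF7 (0.221). Other RS3 rows of the same exons were near 0 for PDHA1 (-0.009), TIRAP (0.02) and IRF7 (0.002) in the authors' deposited table.

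Several of the largest RS3 losses lie in zinc-finger genes, and the hypothesis was that genes with ZNF symbols have called events more often than matched genes. This was not borne out: 10 of 331 such genes (3.02%) had a called event, and 2459 of 10000 random lists matched on events per gene reached that count. The called ZNF events had a median absolute difference of 0.356, against 0.192 over all called RS3 events in the authors' deposited table, a contrast that was not tested.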
